A study of Homo sapiens with 2 samples.

How the data were processed

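RNA was measured on 2 one-colour Agilent arrays, 1 from a control culture and 1 from a culture of the MCF-7 human breast cancer line exposed to blackcurrant extract. Per the labels' protocols, total RNA was labelled with Cy3 and the cells were in their final medium for 24 h. Each group therefore holds 1 array, and nothing in the data measures the spread between cultures.

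Spot intensities were read by the authors with Agilent Feature Extraction, version 10.10 per the submitters' processing notes and module version 10.7 per the file headers. The deposited processed intensity of a spot is background-subtracted and detrended within its array, with low values replaced by a surrogate, per the file headers, and is not scaled between arrays. The deposited mean spot and local background intensities are raw brightness values. The files also hold the deposited p-value of each spot against its background and 0 or 1 calls made from such comparisons, of which only the calls were used here. The authors' value table holds linear processed intensities with no scaling between arrays. It equalled the scanner value within a relative tolerance of 0.0001 for all 49697 probes with a single spot on both arrays, and for 10 and 7 of 1040 probes with repeated spots. The median of its values was 30.7 for control and 20.1 for blackcurrant. How it combined repeated spots stays unknown. It was used as an alternative.

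Each array held 62976 spots, of which 58717 were not control spots. They made up 50599 probes of 60 nt, 49697 with 1 spot and 902 with 10 spots. Of the spots that were not controls, 51.7% on the control array and 47.7% on the blackcurrant array were well above background by the Feature Extraction call. No such spot was saturated, and 372 and 349 spots with an outlier flag were left out. The 75th percentile of probe signal was 399 on the control array and 257 on the blackcurrant array. Both arrays lay on the same slide and were scanned in the same run, so neither separates them. Any difference between the samples in culture, RNA extraction or labelling coincides with the groups.

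The log2 of the processed intensity was averaged over the spots of a probe, and the 75th percentile over all probes that were not controls was subtracted on each array. A probe was kept if it was well above background on both arrays and not saturated on both, which left 21373 probes. The value of a gene is the mean over its kept probes of the log2 difference, blackcurrant minus control. Of 3511 genes with 2 or more kept probes, 1301 had probes on both sides of 0. Probes were named through a RefSeq gene table (GRCh38.p14), used for names only. It named 28174 probes by accession, 2618 by the symbol in the file and 620 by an older symbol, while 324 probes kept the name in the file and 18863 had no gene name. Probe coordinates are those of the files, on hg19.

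With 1 array per group no test was made and no p-value is given, since genes are not replicates. Genes were counted where the difference was at least 2-fold. Technical spread was taken as the within-array SD of repeated spots and as the pooled SD between different probes of a gene. A difference was called larger than the technical spread where it exceeded 2 times the larger of these. A gene with no probe well above background on 1 array and at least 1 on the other was given only as "at least N-fold". That bound sets its brightest probe on the bright array against the higher of the probe's own signal on the dim array and the lowest signal well above background there.

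Before the data were examined, 33 gene lists with 599 entries were fixed. They covered estrogen-induced and estrogen-repressed genes, luminal identity, steroid metabolism, aryl hydrocarbon receptor (AHR), NRF2, ATF4 and p53 targets, metallothioneins, cholesterol synthesis, fatty acid synthesis and oxidation, and DNA replication. They also covered mitosis, the BCL2 family, endoplasmic reticulum chaperones, heat shock, hypoxia, glycolysis, oxidative phosphorylation, interferon response, NF-κB, immediate early genes, autophagy and lysosome, extracellular matrix, ribosomal proteins and housekeeping genes. Markers of mesenchymal, basal or myoepithelial, fibroblast, leukocyte, endothelial and adipocyte cells completed them. A list's median was set against 10000 random lists of the same size drawn from measured genes within the same 10 level groups. A list stood apart where its percentile was under 2.5 or over 97.5, and lists with under 5 measured members got values only. The percentile describes these 2 arrays. A further 7 lists were written after the data were seen.

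The genes named were fixed by a rule. It took the 12 largest differences each way among genes at or above the median level whose probes all went the same way, leaving out names of uncharacterised loci. It added the 2 largest differences each way in each list with 5 or more measured members. It also took a set of 16 fixed genes (ESR1, ESR2, PGR, TFF1, GREB1, CXCL12, CCND1, MYC, CYP1A1, CYP1B1, NQO1, HMOX1, HMGCS1, LDLR, CDKN1A and MKI67) and the 5 largest bounds each way among genes measured on 1 array only. ESR2 was not well above background on both arrays and has no value here.

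On simulated arrays of the 13291 measured genes with a noise SD of 0.1 on the log2 scale, the gene summary recovered 100% of genes planted with a 4-fold change and 94% of those planted with a 2.3-fold change, and called 0% of unchanged genes. Of 100 unchanged lists of 20 genes, 6 fell outside the percentile limits. The simulated noise was smaller than the technical spread of the real arrays, and members of a simulated list did not vary together. With so little noise the gene results were set in advance. The simulation therefore checks the calculation only and gives no error rate for the real arrays.

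The alternatives tried were normexp background correction with an offset of 50, the median of kept probes, quantile normalization, loess on level, no scaling, scaling to the spike-in probes, no filter and a stricter filter on dim probes, the brightest or the median probe per gene, the value table, thresholds of 1.5-fold and 3-fold, another detection call and random lists not matched on level. Scaling to the 75th percentile of detected probes, loess on probe GC content and loess on the position of the probe in its transcript were added after the data were seen. Random lists under the alternatives numbered 2000. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.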

Results

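Gene expression was measured in MCF-7 cells, an estrogen receptor-positive human breast cancer line, after 24 h in medium without serum or phenol red. The medium of 1 culture held 50 μg/ml of blackcurrant extract, a mixture from a berry rich in anthocyanins, and that of the other held none. Each culture gave 1 array, so every difference below compares these 2 arrays and has no replicate check. The number of arrays limits the precision of all values. The comparison asks which transcripts differ between cells with and without the extract. Serum and phenol red can themselves act on the estrogen receptor, so the design also allows estrogen-responsive genes to be compared without them.

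Relative to the bulk of each array, lists higher with blackcurrant extract included glycolysis, hypoxia, immediate early genes, ATF4 targets and NRF2 targets. Metallothioneins were lower. Of 13291 genes measured on both arrays, 1292 (9.72%) were at least 2-fold higher and 1134 (8.53%) at least 2-fold lower. The highest values among genes at or above the median level were those of RASD1, a Ras-related small GTPase, which was 29.4-fold higher, and CGA, the common alpha subunit of the glycoprotein hormones, which was 23.3-fold higher. LDHA, which converts pyruvate to lactate, was 21.1-fold higher, and both of its probes were higher (log2 differences of 4.25 and 4.55). HMOX1, which degrades heme, was 19.9-fold higher, and SLC7A11, which imports cystine, was 16.1-fold higher. ISG20, an exonuclease, was 12.8-fold higher. The transcription factors FOS and ATF3 were 12.7-fold and 11.3-fold higher and EGR1 had a log2 difference of 3.42, while the 3 probes of ATF3 ranged from 1.59 to 4.81 on the log2 scale. The aldolase gene ALDOC, the cytochrome P450 gene CYP1A1 and SLC7A5, which carries large neutral amino acids, were each between 10.4-fold and 10.5-fold higher.

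PSCA, which encodes a cell surface antigen, was 38.3-fold lower than control, the lowest value of all measured genes. TMT1A, named METTL7A on the array, was 21.7-fold lower. PNPLA7, a lysophospholipase, was 11.7-fold lower, and the potassium channel gene KCNJ8, SELENBP1, a selenium-binding protein, and the glutamate receptor gene GRM4 had log2 differences of -3.46, -3.44 and -3.44. PLEKHA6, RAB26, IGDCC3, HMCN1, CRAT and RETREG1 (FAM134B on the array) were between 9.58-fold and 7.45-fold lower. Each of these 12 genes rested on 1 probe, as did all of the higher genes named above except LDHA and ATF3. On hg19, the probe of RASD1 lay on chromosome 17 from 17397787 to 17397846, that of HMOX1 on chromosome 22 from 35790122 to 35790181, that of CYP1A1 on chromosome 15 from 75012562 to 75012621 and that of PSCA on chromosome 8 from 143763976 to 143764035.

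**Figure D1:**
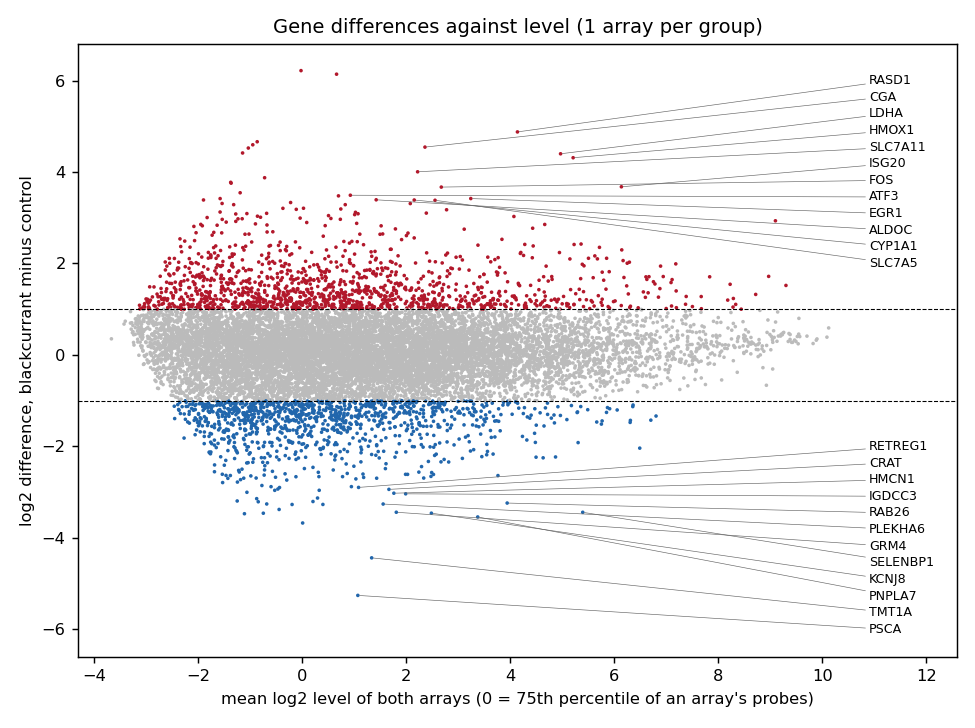
Each point is 1 of the 13291 measured genes, with its mean log2 level over both arrays on the x axis and its log2 difference, blackcurrant minus control, on the y axis. Red points are the 1292 genes at least 2-fold higher, blue points the 1134 at least 2-fold lower, dashed lines mark 2-fold, and lines lead to the 12 largest differences each way among genes at or above the median level, from RASD1 at 4.88 to PSCA at -5.26.

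Glycolysis and hypoxia genes were higher together. Of 16 measured glycolysis genes 11 were at least 2-fold higher and none that much lower, with a median log2 difference of 1.46 (percentile 100 among random lists). Their median was 0.82 without scaling (5 higher and 1 lower by 2-fold or more) and 0.60 with spike-in scaling (4 and 1). ENO2, a neuronal enolase, was 11.1-fold higher beside LDHA and ALDOC, while PFKM and HK1 had log2 differences of -0.60 and -0.05. Of 17 measured hypoxia response genes 11 were at least 2-fold higher and none that much lower, with a median of 1.95 (percentile 100). That was 1.31 without scaling (9 higher and 0 lower) and 1.09 with spike-in scaling (9 and 0). ADM, the precursor of adrenomedullin, was 6.76-fold higher and P4HA2, a collagen prolyl hydroxylase, 6.34-fold higher, while EGLN3 was at -0.04. Oxidative phosphorylation genes did not stand apart. Their median was 0.21 (percentile 66.3), and it was below 0 without scaling and with spike-in scaling and after quantile normalization, with 2 of 26, NDUFA9 and ATP5F1B, at least 2-fold higher and SDHD and NDUFB5 at -0.44 and -0.41. Without scaling and with spike-in scaling none was at least 2-fold higher, while 2 and 7 were at least 2-fold lower. Fatty acid oxidation genes had a median of 0.08 (percentile 51.5), which was below 0 without scaling and with spike-in scaling, and after normexp correction, quantile normalization and loess on level or GC content. PLIN2, a lipid droplet coat protein, was at 3.33, ANGPTL4 was 4.15-fold higher, and ACOX1, a peroxisomal oxidase, was 2.31-fold lower. ACADM was at -0.88.

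NRF2 targets, which serve defence against oxidants and electrophiles, were higher, with 11 of 22 at least 2-fold higher, none that much lower and a median of 1.10 (percentile 100). Without scaling the median was 0.46 (8 higher and 1 lower) and with spike-in scaling 0.24 (6 and 2). HMOX1 and SLC7A11 led them, while NQO1 and EPHX1 were at -0.36 and -0.51. The 6 measured AHR targets had a median of 0.84 (percentile 99.2), or -0.02 with spike-in scaling. As 3 members were above 0 and 3 below (quartiles -0.35 and 2.18), the median of 0.84 lies in the gap between them. CYP1A1 was 10.5-fold and CYP1B1, a related P450, 4.73-fold higher, whereas AHRR, which encodes a repressor of the receptor, was 8.02-fold lower. AHRR rested on 1 probe that was dim on the blackcurrant array, with a log2 level of -2.56. All 8 measured metallothioneins, small proteins that bind zinc and copper, were at least 2-fold lower, with a median of -2.05 (percentile 0). With no filter on dim probes 10 metallothioneins had a median of -1.29 (percentile 0), with 6 at least 2-fold lower, 1 at least 2-fold higher and 3 above 0. MT1B was 4.67-fold lower and the pseudogene MT1L 4.54-fold lower, and since these genes are close copies their single values are uncertain. Of the 2 probes of MT1X, named after its values were seen, 1 was at -0.58 and the other at -1.99.

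Of 19 measured ATF4 targets, which respond to amino acid and endoplasmic reticulum stress, 12 were at least 2-fold higher and none that much lower, with a median of 1.63 (percentile 100), or 0.996 without scaling (9 higher and 0 lower) and 0.77 with spike-in scaling (7 and 0). SLC7A11 and ATF3 were the highest and STC2 was at -0.08. Endoplasmic reticulum chaperones had a smaller median of 0.63 (percentile 99.8), below 0 without scaling and with spike-in scaling, with 2 of 17, DNAJC3 and HYOU1, at least 2-fold higher and the main chaperone gene HSPA5 at -0.53. SEL1L was at -0.29. Heat shock genes had a median of 0.77 (percentile 99.96), or -0.09 with spike-in scaling, with 5 of 15 at least 2-fold higher, among them DNAJA1 (log2 difference 1.63) and HSP90AA1 (3.03-fold). The 3 probes of HSP90AA1 ranged from 0.89 to 2.15 on the log2 scale. BAG3 and HSPB1 were at -0.70 and -0.05.

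Of 19 immediate early genes, which respond within minutes to growth signals or stress, 14 were at least 2-fold higher and none that much lower, with a median of 1.80 (percentile 100), or 1.17 without scaling (10 higher and 1 lower) and 0.94 with spike-in scaling (9 and 1). FOS and ATF3 were the highest, and SPRY2 was at -0.44. Of the NF-κB list 11 of 21 genes were not well above background on either array. Among the 8 measured, 5 were at least 2-fold higher, with a median of 1.47 (percentile 100), led by TNFAIP3 (13.7-fold), an inhibitor of NF-κB signalling, and RELB (3.78-fold), while NFKB1 was at -0.56. With no filter on dim probes all 21 members had a median of 0.76 (percentile 100), and 9 of them were at least 2-fold higher. Relative to all genes that median was 0.47, against 1.40 for the 8 measured. For the 8 measured the median was 0.83 without scaling (4 higher and 1 lower) and 0.61 with spike-in scaling (2 and 1). Interferon response genes had a median of -0.22 (percentile 7.04) with HERC5 and OASL 2.46-fold and 2.32-fold higher, IFI6 2.57-fold lower and IFIT1 at -0.84. HERC5 rested on 1 probe that was dim on the control array, with a log2 level of -3.13. Autophagy and lysosome genes had a median of 0.23 (percentile 77.1), below 0 without scaling and with spike-in scaling. SQSTM1, an autophagy receptor, was 3.27-fold and GABARAPL1 3.12-fold higher, while ATG5 and LAMP2 were at -0.97 and -0.16, and the 3 probes of LAMP2 lay on both sides of 0.

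Cholesterol synthesis genes were higher, with 14 of 23 at least 2-fold higher, none that much lower and a median of 1.07 (percentile 100). The median was 0.44 without scaling (8 higher and 1 lower) and 0.21 with spike-in scaling (4 and 1). HMGCS1, an early enzyme of the pathway, was 6.26-fold, MSMO1 5.26-fold and LDLR, the receptor for low-density lipoprotein, 2.02-fold higher, while TM7SF2 and LSS were at -0.98 and -0.11. Of 11 fatty acid synthesis genes 7 were at least 2-fold higher, none that much lower, with a median of 1.2 (percentile 100), or 0.57 without scaling (2 higher and 1 lower) and 0.34 with spike-in scaling (1 and 2). SCD, the desaturase that makes oleate, was 4.11-fold and ME1 3.55-fold higher, whereas FASN and SREBF1 were at -0.60 and -0.29. With a stricter filter on dim probes 9 of these genes were left, with a median of 0.43 above that of all genes, and the list no longer stood apart (percentile 96.3).

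Estrogen-induced genes had a median of 0.53 (percentile 99.99), below 0 without scaling and with spike-in scaling, with 11 of 36 at least 2-fold higher and 3 lower. TFF1, a secreted trefoil peptide, was 3.29-fold higher, GREB1 2.79-fold and the chemokine gene CXCL12 2.26-fold. The 3 probes of GREB1 ranged from 0.50 to 2.71 on the log2 scale. RAB31 was 3.54-fold and HSPB8 3.35-fold higher. HSPB8 rested on 1 probe that was dim on the control array, with a log2 level of -2.89. ELOVL2 was 3.34-fold and MYB 2.43-fold lower. PGR, the progesterone receptor gene, was at 0.17 with 1 of its 2 probes on each side of 0, CCND1 at -0.05 and MYC at 0.77. The receptor gene ESR1 was at -0.39, and its 3 probes ranged from -0.78 to 0.37. Estrogen-repressed genes had a median of -0.70 (percentile 0.51), with 4 of 10 at least 2-fold lower and none that much higher. PSCA and YPEL3 (3.49-fold) were the lowest, and BIK and CCNG2 were at 0.58 and 0.52. With the stricter filter 6 of these genes were left, 1 of them at least 2-fold lower, and their median lay 0.047 above that of all genes. Luminal identity genes had a median of -0.16 (percentile 6.02), with TFAP2C 2.66-fold higher, SPDEF 3.76-fold and the androgen receptor gene AR 2.72-fold lower, and XBP1 at 0.93. Steroid metabolism genes had a median of -0.14 (percentile 20.1), or 0.26 with no filter on dim probes, which was -0.04 relative to all genes. AKR1C1, whose close copies make its value uncertain, was 6.83-fold and HSD17B7 3.21-fold higher, UGT2B15 was 2.11-fold lower and COMT was at -0.97.

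DNA replication genes had a median of 0.63 (percentile 100), below 0 without scaling and with spike-in scaling, with 7 of 31 at least 2-fold higher and none that much lower. POLE2, a DNA polymerase subunit, was 7.29-fold and RRM2, a ribonucleotide reductase subunit, 4.85-fold higher, while DHFR and POLA1 were at -0.24 and -0.22. Mitosis genes had a median of 0.43 (percentile 99.6), below 0 without scaling and with spike-in scaling, with 6 of 30 at least 2-fold higher, led by TOP2A (3.48-fold) and BUB1B (2.95-fold). MKI67 was at 0.51, HMMR at -0.55 and CENPE at -0.28. Targets of p53 had a median of 0.19 (percentile 75.4), below 0 without scaling and with spike-in scaling, with members on both sides of 0. GDF15, a stress-induced cytokine, was 7.64-fold, PLK3 3.88-fold and the cell cycle inhibitor gene CDKN1A 2.88-fold higher, while BTG2 was 2.49-fold and SPATA18 2.24-fold lower. The BCL2 family had a median of 0.58 (percentile 99.5), below 0 without scaling and with spike-in scaling, with PMAIP1 (4.86-fold) and HRK (2.56-fold), both promoters of cell death, among 3 of 14 at least 2-fold higher, and BCL2A1 and BMF at -0.86 and -0.77.

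The median of housekeeping genes was 0.94 (percentile 99.98), or 0.30 without scaling (1 higher and 1 lower) and 0.08 with spike-in scaling (0 and 2). Scaled to the 75th percentile, 5 of 13 were at least 2-fold higher, among them PGK1 and ACTB, which was 3.28-fold higher, while GUSB and SDHA were at -0.44 and -0.17. All 43 ribosomal protein genes were above 0 and none reached 2-fold, with a median of 0.30 (percentile 92.1) and RPS21 and RPL32 highest at 0.85 and 0.79. That median was -0.04 after quantile normalization, -0.05 after loess on level, -0.34 without scaling and -0.56 with spike-in scaling. Extracellular matrix genes had a median of -0.09 (percentile 18.3), which was 0.01 after normexp correction and 0.11 with no filter on dim probes. With no filter the median of all genes was 0.29, against 0.08 with it. Relative to all genes the list was then at -0.19, against -0.17. LOXL2 was 4.94-fold and LAMA3 3.86-fold higher, COL12A1 7.63-fold and LAMB2 2.40-fold lower. The 2 probes of LAMA3 were at 0.88 and 3.02.

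Markers of other cell types were mostly not well above background. On both arrays 3 of 12 mesenchymal markers were measured, 2 of 8 basal or myoepithelial, 1 of 8 fibroblast, 2 of 7 leukocyte, 1 of 5 endothelial and 1 of 5 adipocyte markers, with medians of 0.19, 0.18, -0.19, 0.04, 0.68 and 0.11. Of the leukocyte markers, 1 (CD68) was measured on the blackcurrant array only and 2 (CD2 and PTPRC, named after their values were seen) on the control array only.

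**Figure D2:**
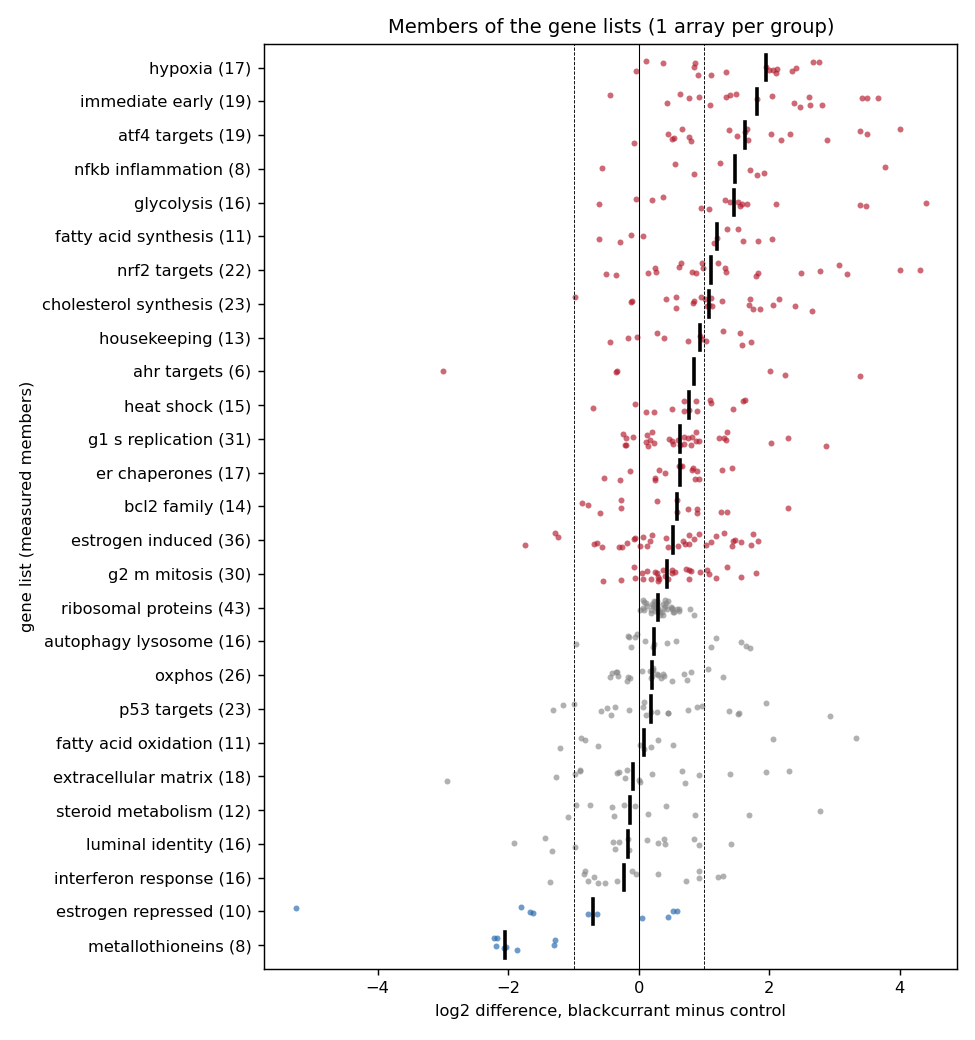
Each row is a gene list fixed in advance with 5 or more measured members (number in brackets), each point a member with its log2 difference, blackcurrant minus control, on the x axis, and each black bar the list's median; vertical position within a row has no meaning. Red lists stood apart as higher and blue lists as lower than random lists, grey ones did not, and medians, scaled to the 75th percentile, run from 1.95 for hypoxia to -2.05 for metallothioneins.

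Genes measured on 1 array only have bounds in place of values. With blackcurrant extract only, 392 genes were well above background, 353 of them with a bound of at least 2-fold. The highest bounds were those of ZNF208 (at least 47.2-fold), AREG, which encodes amphiregulin (at least 37.5-fold), the pseudogene C3P1 (at least 33.4-fold), CD68 (at least 28.9-fold) and BABAM2-AS1 (at least 27.7-fold). In the control only, 1224 genes were well above background, 450 of them with a bound of at least 2-fold. The blackcurrant array was dimmer (75th percentile of 257 against 399), so more genes could fall below the call there. With the other detection call the genes with such a bound numbered 516 (blackcurrant only) and 400 (control only), the reverse order. SELENOP, a plasma selenoprotein, was at least 25.9-fold higher in the control, GMCL2 and CNPY4 at least 25.8-fold, STARD6 at least 23.9-fold and LINC00460 at least 23.2-fold.

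Repeated spots of a probe had an SD of 0.12 on the control and 0.14 on the blackcurrant array, and the pooled SD between probes of a gene was 0.59. The limit of 2 times that SD was 1.18, which 890 genes exceeded as higher and 818 as lower. Among the genes at least 2-fold apart named above, LDLR, ATP5F1B, CXCL12, UGT2B15 and SPATA18 did not exceed it. Of 429 genes at least 2-fold apart with 2 or more probes, 11 had probes on both sides of 0, against 1301 of all 3511. Choosing genes by a mean of at least 2-fold makes this rare by itself, so it is no measure of probe agreement. The direction of the whole set depended on the scaling. Scaled to the 75th percentile, 53.3% of the genes at least 2-fold apart were higher. Without scaling 407 were higher and 3521 lower (10.4% higher), and with scaling to the 7 spike-in probes above background 268 were higher and 5009 lower (5.08% higher). Spike-in scaling moved all genes by -0.86 and no scaling by -0.64, so the differences given here are relative to the bulk of each array. With spike-in scaling 0 estrogen-induced genes were at least 2-fold higher and 9 lower, with 3 and 4 for replication, 0 and 2 for mitosis, 0 and 3 for endoplasmic reticulum chaperones, 0 and 1 for heat shock, 1 and 5 for the BCL2 family and 3 and 3 for AHR targets. The counts were 2 and 8 for p53 targets, 0 and 3 for autophagy, 2 and 4 for fatty acid oxidation, 0 and 9 for luminal identity, 1 and 6 for steroid metabolism, 0 and 8 for interferon response and 2 and 9 for extracellular matrix. They were 0 and 6 for estrogen-repressed genes, 0 and 8 for metallothioneins and 0 and 0 for ribosomal proteins.

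The difference also varied with where a probe lies in its transcript. Probes starting in the first 300 nt had a median of 0.41, those from 2001 to 4000 nt -0.01 and those beyond 7000 nt -0.38. Within 2178 transcripts with probes at least 300 nt apart, the probe nearer the 3′ end was lower than the other by a median log2 difference of -0.40 (quartiles -0.88 and -0.05), and it was the lower one in 78.0% of them. After loess on position, 1106 genes were at least 2-fold higher and 1169 lower, of which 1023 and 1001 were among those counted above. Hypoxia then had a median of 1.95, immediate early genes 1.79, the NF-κB list 1.49, ATF4 targets 1.47, fatty acid synthesis 1.29, glycolysis 1.28, cholesterol synthesis 1.13 and NRF2 targets 0.95. AHR targets were at 0.83, housekeeping genes 0.81, heat shock 0.68, endoplasmic reticulum chaperones 0.63, replication 0.54, estrogen-induced genes 0.49, the BCL2 family 0.44 and mitosis 0.34. Estrogen-repressed genes were at -0.72 and metallothioneins at -2.34. Ribosomal proteins, whose probes start at a median of 446 nt, were at 0.09.

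**Figure D3:**
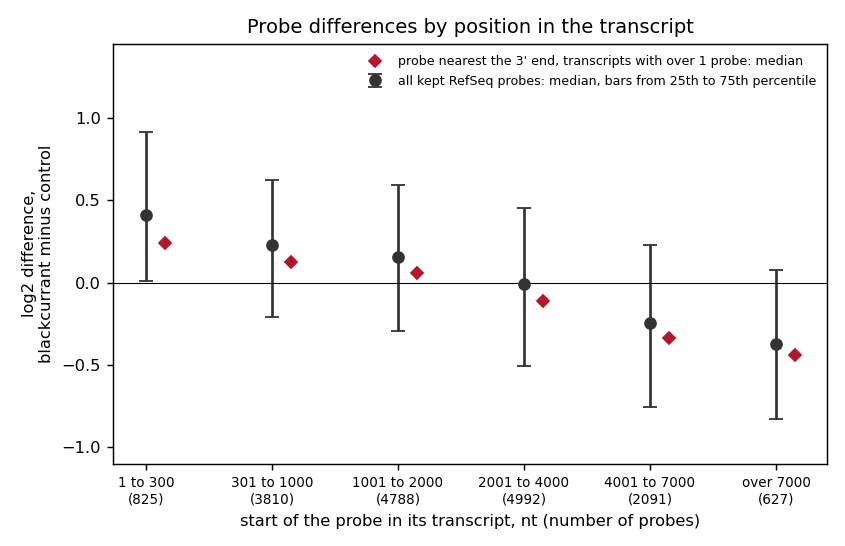
Kept RefSeq probes are grouped on the x axis by the start of the probe in its transcript (nt, number of probes in brackets), and the y axis gives the log2 difference, blackcurrant minus control. Black points are medians with bars from the 25th to the 75th percentile, falling from 0.41 to -0.38, and red diamonds are medians of the probe nearest the 3′ end in transcripts with over 1 probe, from 0.24 to -0.44.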

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

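Probes without a gene name entered no comparison of the report, yet 350 of the 3469 kept ones were at least 2-fold higher with blackcurrant extract and 317 at least 2-fold lower. These shares are near those of named genes (9.72% and 8.53%). The median log2 difference was 0.21 over unnamed probes and 0.08 over named genes, where single probes and gene means are unlike units. The unnamed probes are signal in data left unused, and no explanation was tested. Groups of 1 array allow no check for outlying samples and no comparison of effects between groups.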

How the results depend on the processing

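Of the alternatives, 3 were chosen after the data were seen: scaling to detected probes, loess on probe GC content and loess on probe position. The counts of genes at least 2-fold higher with blackcurrant extract (1292) and of genes at least 2-fold lower with blackcurrant extract (1134) stayed within 1.5 times under these 3, and under the median of kept probes, quantile normalization, loess on level, the brightest or median probe and the value table. They were 785 higher under normexp correction, 407 and 3521 without scaling, 268 and 5009 with spike-in scaling, 2265 and 1851 with no filter, 593 and 444 with the stricter filter, 2917 and 2410 at 1.5-fold, and 446 and 364 at 3-fold. The fold thresholds and filters change the counts by construction, the filters in part through the number of genes kept (21634 and 7953, against 13291). With the stricter filter both counts fell by a larger share than the number of genes, so that number alone does not account for the fall. One factor for all genes moves the counts under no scaling and spike-in scaling. Normexp correction adds an offset of 50 to every intensity, which by construction makes log2 differences of dim probes smaller. Its share in the lower count was not tested. Genes measured on 1 array only with a bound of at least 2-fold numbered 516 (blackcurrant) and 400 (control) with the other detection call, against 353 and 450. List medians were taken relative to all genes. The 4 settings that move all genes alike (median of kept probes, no scaling, spike-in scaling and detected probes) cannot change these and are left out here. Of 178 other recomputed medians of the 18 lists that stood apart, 176 kept their direction and their side of the limits. Among these settings, the value table held the scanner values of single spots. The median of probes equals the mean for genes with 1 or 2 probes. Both could therefore move a list median only little. With the stricter filter, estrogen-repressed genes turned to 0.047 on 6 of 10 genes, PSCA being among those left out, and fatty acid synthesis was at 0.43 on 9 of 11. The stricter filter left AHR targets and the NF-κB list without a value. With no filter the medians of the NF-κB list and metallothioneins, not relative to all genes, were 0.76 and -1.29 against 1.47 and -2.05. Relative to all genes they were 0.47 and -1.59 against 1.40 and -2.13. Lists that did not stand apart kept that in 88 of 90 cases, the others being ribosomal proteins with no filter and luminal identity with the stricter filter. Without these 4 settings, of 1205 values of 124 named genes 1166 kept their side of 2-fold, 23 fell below it, 16 passed it and 0 changed sign among genes at least 2-fold apart. Signal over background limits how many list members can be measured, as dim genes drop out. No paired analysis was possible because each group holds 1 array, and leaving out a replicate was not possible for the same reason.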

Other observations

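In this part, the 7 lists of the next paragraph and the tests on spike-ins, on RNA input and on probe position were chosen after the data were seen. The genes named here that the report does not hold were too.

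Tubulins were higher with blackcurrant extract, with 10 of 11 measured genes at least 2-fold higher and a median log2 difference of 1.81 (percentile 100), led by TUBA4A at 3.09 and TUBB2A at 2.40. Their close copies make single values uncertain. Proteasome subunits had a median of 0.84 (percentile 100), with 10 of 31 at least 2-fold higher, none that much lower and PSMD11 highest at 2.01. Cytosolic tRNA synthetases, which load amino acids onto tRNA, had a median of 0.82 (percentile 100), with 8 of 20 at least 2-fold higher and GARS1 highest at 1.99. With spike-in scaling the proteasome and tRNA synthetase medians were -0.03 and -0.04, and that of tubulins 0.95. The numbers at least 2-fold higher and lower were then 1 and 0 for the proteasome, 2 and 1 for tRNA synthetases and 5 and 0 for tubulins, and without scaling 2 and 0, 2 and 1, and 7 and 0. After loess on probe position the 3 medians were 1.70, 0.66 and 0.71. Clock genes had a median of -0.25 (percentile 9.99), with RORC, CRY2 and DBP at -2.20, -2.20 and -2.19 and BHLHE40 at 3.05. FOXO targets had a median of 0.30 (percentile 81.4) and zinc transporters 0.28 (percentile 84.3), both below 0 without scaling and with spike-in scaling, and iron handling genes -0.13 (percentile 14.7), or 0.03 with the stricter filter. Below the median level, INHBA, a subunit of activins, was at 6.22 and GEM, a small GTPase, at 6.14, above every gene measured on both arrays that the report names.

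The processed signal of genes was lower on the blackcurrant array by a median of -0.56, while the 7 spike-in probes were higher by a median of 0.20 (range 0.10 to 0.32). Weaker hybridisation or washing of the whole array would have lowered the spike-ins too, and they were not lower. As this comparison was chosen after these values were seen, it restates the pattern and is no independent test. Loss of 5′ sequence on the blackcurrant array would have left the 3′ probe relatively higher, whereas it was lower by a median of -0.40 (random order gave -0.04 to 0.04). After spike-in scaling the median gene difference was -0.79, and unequal RNA input or labelling cannot be told apart from less mRNA per total RNA, since both change all genes by 1 factor on 1 array. The opposite trend along transcripts may come from more fragmented control RNA or from use of other 3′ ends, and neither was tested. Medians of the probes nearest the 3′ end also fell with their start, from 0.24 (26 probes) to -0.44. Position was counted from the 5′ end, so across transcripts it cannot be told apart from transcript length.

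Hypoxia and glycolysis genes were higher together. After loess on level the lower of the 2 list medians was 1.19 above that of all genes, after loess on GC content 1.32 and after loess on probe position 1.26, which argues against these trends as the whole cause. Iron limitation, which stabilises the hypoxia-inducible factor and the transferrin receptor mRNA, is a candidate explanation. TFRC was at 1.94 on 1 probe, as that hypothesis needs, but TFRC also responds to the hypoxia-inducible factor, and SLC11A2, another iron transporter, was at 0.16. The extract itself and oxygen use by denser cells stay open and untested.

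All 8 measured metallothioneins were lower, while with no filter on dim probes 3 of 10 were above 0. The lowest identity among the 36 pairs of their 9 probes was 28.3%, and 26 pairs under 70% had both probes at least 2-fold lower. Probes were compared with each other and not with transcripts, and the 2 probes of MT1X were themselves only 33.3% identical. Low identity therefore cannot decide whether several probes read 1 transcript. After loess on level the median of metallothioneins was -2.15 against all genes, so a trend with level is not the whole cause. Zinc limitation, for example by binding of zinc to extract compounds, may lower them, and SLC30A1, another target of the zinc sensor MTF1, was at -0.58 on 1 probe, at the bound set for it and within the technical limit of 1.18, which decides nothing. SLC39A10, a zinc importer, was at 2.36, and the extract itself stays open as the origin.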
